A study of Mus musculus with 24 samples.

How the data were processed

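The deposited tables held T cell receptor clonotypes, 1 table per library, each row giving a V segment, a J segment, a CDR3 nucleotide sequence, its amino-acid translation and a count. Each count was, per the labels, the number deposited for that clonotype, used as a raw, unscaled count. The genome build was mm10 according to the submitters' processing notes. The aligner and the clonotype caller, with their versions, were not given in the sources used here. The gene table used for coordinates was of GRCm38.p6, the same build, and no reads were realigned.

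The 24 tables held 156507 rows with a total count of 251695. Rows with an out-of-frame CDR3 numbered 99, with 99 counts, 0.0633% of the rows and 0.0393% of the counts. They lay in 18 libraries, 0 to 15 in each, and were left out except in 1 alternative. No row held a stop codon. Rows that repeated the V, J and nucleotide sequence of another row of the same table numbered 101, and their counts were added. Of the names in the tables, 105 of 106 alpha V, 43 of 43 alpha J, 30 of 36 beta V and 12 of 12 beta J segments were found in the gene table, and the matched names held 99.988% of the V counts of each chain. Some names were listed in libraries of 1 sort only: in the beta GFP-negative libraries 6 V names missing from the gene table with 19 counts and 5 others with 23 counts, in the beta GFP-positive libraries 1 V name with 2 counts, and in the alpha GFP-positive libraries TRAV14N-1 with 17 counts and TRAJ47 with 2.

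Depth was read from the productive total of each library. It ran from 2010 to 12213 counts in the alpha libraries (median 8647, n = 12) and from 5192 to 23316 in the beta libraries (median 11501.5, n = 12). Clonotypes seen with a count of 1 made up 26.7% to 86.6% of alpha and 47.9% to 85.0% of beta clonotypes, and the estimated sample coverage was 26.6% to 90.8% and 29.5% to 79.1%. V usage of replicates differed by more than counting error in each of the 24 within-group pairs; the smallest chi-square per degree of freedom was 1.84 (two-sided p = 3.8e-06, B6 GFP-negative alpha replicates 2 and 3).

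Segment usage was tested with edgeR 4.0.16 in R 4.3.3, with quasi-likelihood F-tests, on counts per V and J segment. The 12 libraries of a chain shared 1 fit with a mean per group, the library size was the productive total without TMM factors, and segments with few counts were removed by filterByExpr. This left 129 alpha segments (89 V and 40 J) and 35 beta segments (23 V and 12 J). P values were two-sided and adjusted with the Benjamini-Hochberg method over all V and J segments of a chain in a contrast, at a threshold of 0.05. A log2 fold change is given with its standard error (SE), and a share with the SD over the 3 libraries of a group. The contrasts were NOD against B6 in each sort, GFP-negative against GFP-positive in each strain, and the difference of the strain contrast between the sorts. The GFP-positive sort was taken as the newly developing cells named in the series title; the labels do not define the reporter. The same model was applied to amino-acid clonotypes (V, J and CDR3 amino acids) found widely enough to pass filterByExpr, 6 alpha and 4 beta, with the sort effect averaged over both strains.

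Segments were named in the report by a rule: in each contrast and chain the 10 V and 10 J segments with the largest fold among those with adjusted p under 0.05, a mean share of at least 0.5% in 1 of the groups and no overlap of the 3 libraries of 1 group with the 3 of the other. No overlap arises by chance for 10% of segments. Members of the fixed lists were added, and of the shared clonotypes the 5 with the lowest p in each direction. The lists were Mtv superantigen-responsive V-beta (TRBV26, TRBV12-1, TRBV12-2, TRBV16, TRBV15), Mtv-7-responsive V-beta (TRBV19, TRBV29, TRBV13-3, TRBV17), insulin-recognition V-alpha (TRAV5D-4, TRAV5N-4, TRAV5-4), V-proximal J-alpha (TRAJ45 to TRAJ61), middle J-alpha (TRAJ23 to TRAJ44), V-distal J-alpha (TRAJ2 to TRAJ22), J-proximal V-alpha (TRAV17, TRAV19, TRAV21/DV12), J-distal V-alpha (TRAV1, TRAV2), the first and second D-J-beta clusters (TRBJ1 and TRBJ2 members) and duplicated V-alpha copies (names with D or N). Each list was tested as a set with limma 3.58.1 fry on log2 CPM (prior count 2). That test asks whether the members move one way on balance and does not set them against the other segments. Its two-sided p values were adjusted over 35 alpha and 20 beta tests. Invariant chains were counted by fixed patterns: TRAV11 or TRAV11D with TRAJ18 and a 15-residue CDR3 for invariant NKT cells, and TRAV1 with TRAJ33 and a 12-residue CDR3 for MAIT cells.

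Diversity was computed at equal depth, 2010 counts for alpha and 5192 for beta, as the mean of 20 draws per library (seed 11). The measures were distinct nucleotide clonotypes, the Shannon effective number, the inverse Simpson index and the share of counts in the 10 most abundant clonotypes. The CDR3 features were length, net charge of the centre (K and R minus D and E, without the first 4 and last 4 residues), the share with D or E in the centre, the share with a cysteine inside the CDR3, and the share with hydrophobic residues at positions 6 and 7. These measures were compared with two-sided exact permutation tests, with 20 arrangements for 3 against 3 libraries (smallest p 0.1) and 400 when the labels were permuted within a stratum (smallest p 0.005), adjusted over 16 diversity and 20 feature tests. Overlap of 2 libraries was the number of shared amino-acid clonotypes over the geometric mean of their numbers at equal depth, with the Morisita-Horn index beside it. The sharing of nucleotide clonotypes by B6 and NOD libraries with the same replicate number was compared after results were seen, with all clonotypes and the numbers permuted within a sort. In the same way log2 overlap of B6 with NOD libraries was fitted with the level of each library, and the SD left over was compared within a sort and across sorts with an F-test. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for these steps and the figures.

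The tests, the threshold, the lists and the alternatives named in this paragraph were fixed before the data were examined. Segment usage was repeated with TMM factors, with DESeq2 1.42.0, without a filter, with each clonotype counted once, without clonotypes of count 1, with out-of-frame rows, with D and N copies merged, with replicate number as a block, with the 2 compared groups alone, and with each library left out in turn. Diversity was repeated without equal depth, at a fraction 0.5 of the smallest total, with other clonotype definitions, without count-1 clonotypes, at equal coverage and with the block. Features were repeated with each clonotype counted once, without count-1 clonotypes, with 3 residues left out at each end and with the block. Overlap and shared clonotypes were repeated with other definitions, minimum counts, depths and tools. Added once the data had been seen were repeats without the number-1 libraries, without nucleotide clonotypes found in both strains and without TRBV1, and the same settings for the lists, the same-number overlap and the invariant NKT share.

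The labels do not say that replicates are separate animals, so p values measure the spread between these samples. Sequence shared within a group (up to 42.8%) may narrow that spread. By segment usage replicate numbers paired the libraries in 1 place only. In the beta GFP-positive libraries the segment usage of same-numbered B6 and NOD libraries, each taken as its difference from its own group mean, correlated at 0.68, 0.39 and 0.69 for numbers 1, 2 and 3, and each library correlated best with its own number. With the number as a block 4 of the 5 strain calls there were kept. In each of the other 7 comparisons of numbers at least 1 correlation was under 0.1, and no block was used. Same-numbered B6 and NOD libraries of a sort shared 4.19 times as many alpha nucleotide clonotypes as others, which fits without the block leave out.

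The edgeR test was tested on simulated data for NOD against B6 in the GFP-positive sort. With 24 of 129 alpha segments changed per run over 20 runs, 7.08% of changes of 1.5-fold and 35.4% of changes of 2-fold were recovered, with 5.56% false among the calls. With 6 of 35 beta segments changed, 36.7% and 83.3% were recovered, with 5.26% false. For shared clonotypes changed 8-fold in 100 runs, 6% of alpha and 9% of beta changes were recovered, with 45.5% and 30.8% false among the few calls. The stratified permutation test gave p under 0.05 in 5% of 1000 simulations without a shift and in 99.4% of those with a shift of 3 SD.

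Upper limits given for clonotypes with 0 counts cover counting error only. Counts of near-identical V-alpha copies are uncertain, because a read may be given to either copy. The mean number of inserted nucleotides was not computed, as the tables give no segment ends.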

Results

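T cell receptor alpha and beta chains were sequenced from sorted regulatory T cells of the thymus of C57BL/6 (B6) and non-obese diabetic (NOD) mice, 8-week-old wild-type females. The sort took CD4-positive, CD8-negative, Thy1.1-positive cells and parted them into GFP-positive and GFP-negative cells. There were 24 libraries in 8 groups of 3: 2 strains, 2 sorts and 2 chains. GFP-positive cells stood for the newly developing cells of the series title. The sorts lie in separate ranges of sample numbers, so a sort difference below may be one of submission or processing. The alpha libraries held 1705 to 8151 nucleotide clonotypes and the beta libraries 4308 to 13210.

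How far did libraries share the same nucleotide sequences? In the alpha chain 7838 of 42138 nucleotide clonotypes (18.6%) were found in both strains, and they held 9.32% to 65.0% of the counts of a library (mean 36.5% ± 16.6, SD, n = 12). In the beta chain 4588 of 90749 (5.06%) were found in both strains, with 4.33% to 26.7% of the counts (mean 13.4% ± 7.28, SD, n = 12). The sharing sat in few pairs of libraries. Of 36 alpha pairs of a B6 with a NOD library, 10 shared over 5% of their nucleotide clonotypes, 45.0% at the highest (B6 and NOD GFP-positive replicates 2) against a median of 2.08%, and 9 of the 10 pairs were of the same sort. Of 36 beta pairs 5 shared over 5%, 14.5% at the highest against a median of 0.681%, all 5 of the same sort. Within a strain 5 of 30 alpha pairs and 1 of 30 beta pairs lay over 5%, 42.8% and 18.1% at the highest. Among pairs of a B6 with a NOD library of the same sort, those with the same replicate number shared 21.4% of alpha nucleotide clonotypes on average and those with different numbers 5.10% (ratio 4.19, exact permutation of 36 pairings, one-sided p = 0.0278, the smallest reachable); for beta the shares were 6.42% and 2.36% (ratio 2.72, one-sided exact permutation p = 0.0556). The strain contrasts below hold these shared sequences unless a value is given without them.

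**Figure D1:**
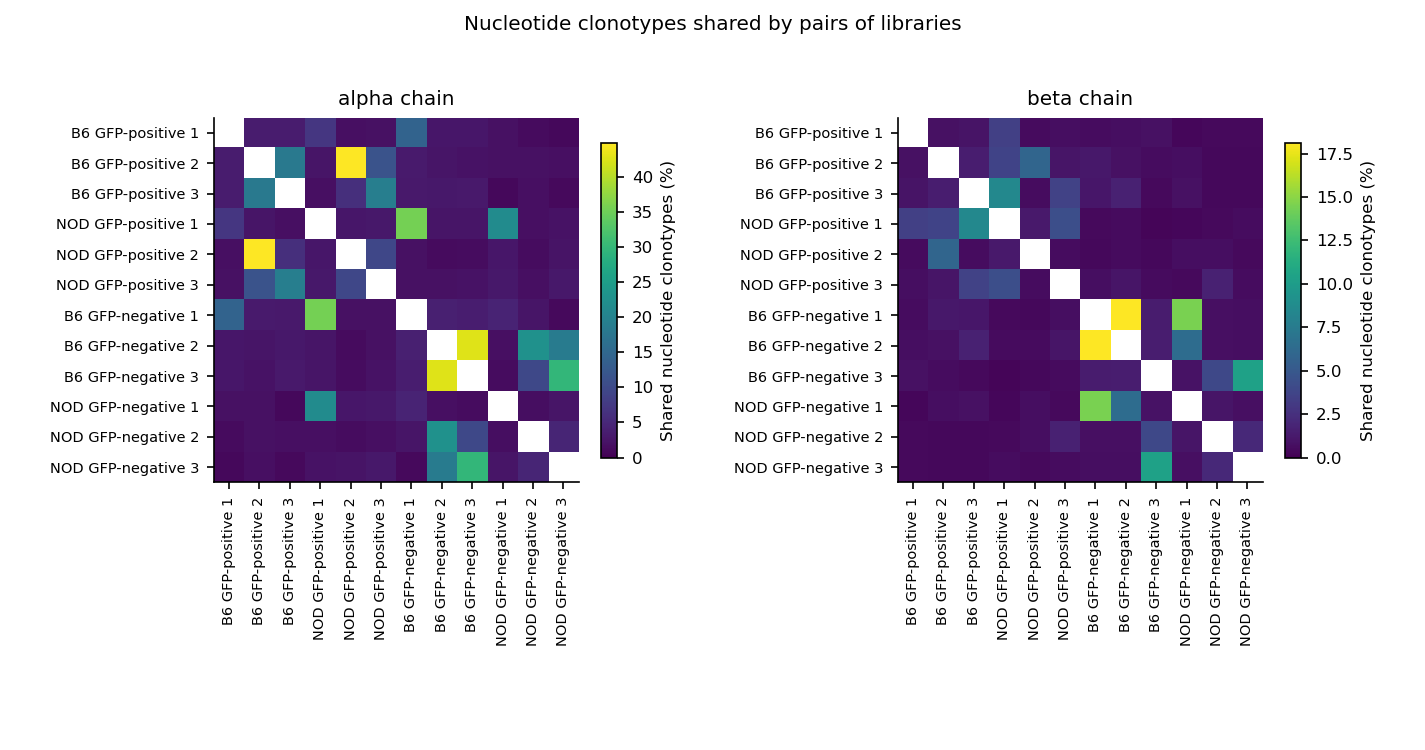
Percent of nucleotide clonotypes shared by each pair of libraries, alpha chain and beta chain, with the 12 libraries of a chain on both axes. Among alpha pairs the highest of different strains reached 45.0% (median 2.08%) and the highest within a strain 42.8%.

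Did newly developing NOD regulatory T cells use other alpha segments than those of B6? Of 129 segments tested, 29 rose and 19 fell in NOD GFP-positive libraries, 48 in all (edgeR, two-sided, adjusted p under 0.05). These were 22 V up and 12 V down of 89, and 7 J up and 7 J down of 40. TRAV14D-2 (chromosome 14, 52948668 to 52949169, mm10) rose 22.2-fold, from 0.0792% ± 0.130 of counts in B6 to 1.86% ± 0.331 in NOD (SD, n = 3 each, log2 4.47, SE 1.2, adjusted p = 0.0165). TRAV12D-3 rose from 0.0683% ± 0.111 to 1.21% ± 0.202 (log2 4.06, adjusted p = 0.0282) and TRAV13-1 from 0.0856% ± 0.139 to 1.51% ± 0.443 (log2 4.07, adjusted p = 0.0282). TRAV15D-1/DV6D-1, TRAV12-2 and TRAV7D-5 rose by log2 3.01, 2.76 and 2.69 (adjusted p = 0.0246, 0.0138 and 0.00768). TRAV14-3 fell from 1.42% ± 0.370 to 0.218% ± 0.199 (log2 -2.69, SE 0.97, adjusted p = 0.0480), and TRAV13-2, TRAV6N-6 and TRAV7N-5 by log2 -2.59, -2.55 and -2.50 (adjusted p = 0.0282, 0.0367 and 0.0369). The 3 libraries of 1 strain did not overlap the 3 of the other for 56 of 89 V (62.9%) and 26 of 40 J (65%), against 10% by chance.

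Many of these V-alpha names have near-identical copies, and with the copies merged 13 of 47 V names passed. Of the 33 called V names with copies 16 kept call and direction and 17 did not, 9 of which turned direction: TRAV13-1 went to log2 -0.15, TRAV12-2 to -0.30 and TRAV14-3 to 0.23. Without nucleotide clonotypes found in both strains 74 segments passed, and the V folds widened, to log2 7.94 for TRAV12D-3 and -8.92 for TRAV6N-6. That setting selects on strain and can widen folds by itself. The 48 calls became 27 with copies merged, 18 without the number-1 libraries, 24 without B6 GFP-positive replicate 1, 19 without B6 GFP-positive replicate 3, 28 without NOD GFP-positive replicate 2 and 25 without NOD GFP-positive replicate 3. Of 6 fits with 1 library left out TRAV7D-5 kept its call in 6, TRAV14D-2 and TRAV12-2 in 4, TRAV13-1 and TRAV15D-1/DV6D-1 in 2, TRAV12D-3, TRAV14-3 and TRAV7N-5 in 1, and TRAV13-2 and TRAV6N-6 in 0.

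The J-alpha segments of NOD GFP-positive cells lay nearer to the V genes. TRAJ45 (54172831 to 54172890, mm10) rose from 0.731% ± 0.194 to 2.69% ± 0.280 (n = 3 each, log2 1.88, SE 0.37, adjusted p = 0.00564), TRAJ35 from 0.478% ± 0.118 to 1.61% ± 0.359 (log2 1.75, adjusted p = 0.00768) and TRAJ48 from 1.31% ± 0.247 to 2.71% ± 0.153 (log2 1.05, adjusted p = 0.00169). TRAJ50, TRAJ52 and TRAJ49 rose by log2 1.05, 0.84 and 0.76. TRAJ6 (54212688 to 54212749) fell from 2.46% ± 0.274 to 1.21% ± 0.0898 (log2 -1.02, SE 0.19, adjusted p = 0.00415), TRAJ22 from 5.64% ± 0.628 to 2.95% ± 0.176 (log2 -0.93, adjusted p = 0.00768), and TRAJ4 and TRAJ9 by log2 -0.99 and -0.67. V-proximal J-alpha segments are used in the first rearrangements of the locus and V-distal ones in later rounds. Leaving out any 1 library ended the call of TRAJ4 and of none of TRAJ45, TRAJ35, TRAJ48, TRAJ50, TRAJ6, TRAJ22, TRAJ49 and TRAJ9; TRAJ52 kept its call in 4 of 6 such fits.

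The J-alpha lists were also tested as sets. V-proximal J-alpha took 9.96% ± 1.74 of B6 and 18.2% ± 0.892 of NOD GFP-positive counts (SD, n = 3 each); 5 of 9 members rose, 5 adjusted over the list alone, and none fell (limma fry, two-sided, adjusted p = 0.00427). V-distal J-alpha went from 39.6% ± 2.33 to 28.5% ± 0.527; 7 of 14 members fell, 7 adjusted over the list alone (fry adjusted p = 0.00265). Middle J-alpha went from 50.5% ± 0.835 to 53.4% ± 0.380, with 2 of 17 members up, 2 adjusted over the list alone (fry adjusted p = 0.0283), and members going both ways (TRAJ32 log2 0.59, TRAJ24 -0.36). That last call ended with TMM factors (0.0520), with each clonotype counted once (0.136), without clonotypes found in both strains (0.0656), and without NOD GFP-positive replicate 1 (0.0894) or 2 (0.104).

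Of the V-alpha lists, TRAV5D-4 (53001713 to 53002231, mm10), a segment found in insulin-recognizing CD4 T cells of NOD mice, was the only tested member of the insulin-recognition list. It rose from 2.43% ± 0.383 to 6.05% ± 1.03 of GFP-positive counts (n = 3 each, log2 1.32, SE 0.36, adjusted p = 0.0175; 1 member up over the list alone, fry adjusted p = 0.0604). No member of J-proximal V-alpha (0 of 3; 2.39% ± 0.593 and 3.26% ± 0.212, fry adjusted p = 0.428) or J-distal V-alpha (0 of 2; 1.24% ± 0.0761 and 1.25% ± 0.111, fry adjusted p = 0.872) passed, and none adjusted over the list alone. Duplicated V-alpha copies held 57.2% ± 1.62 of B6 and 52.9% ± 1.83 of NOD counts; 12 rose, 6 fell and 30 did not pass, the same adjusted over the list alone. Their fry direction was up (adjusted p = 0.873) while median and mean log2 were -0.55 and -0.29, and the mixed fry test, which counts moves either way, gave adjusted p = 0.00185.

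**Figure D2:**
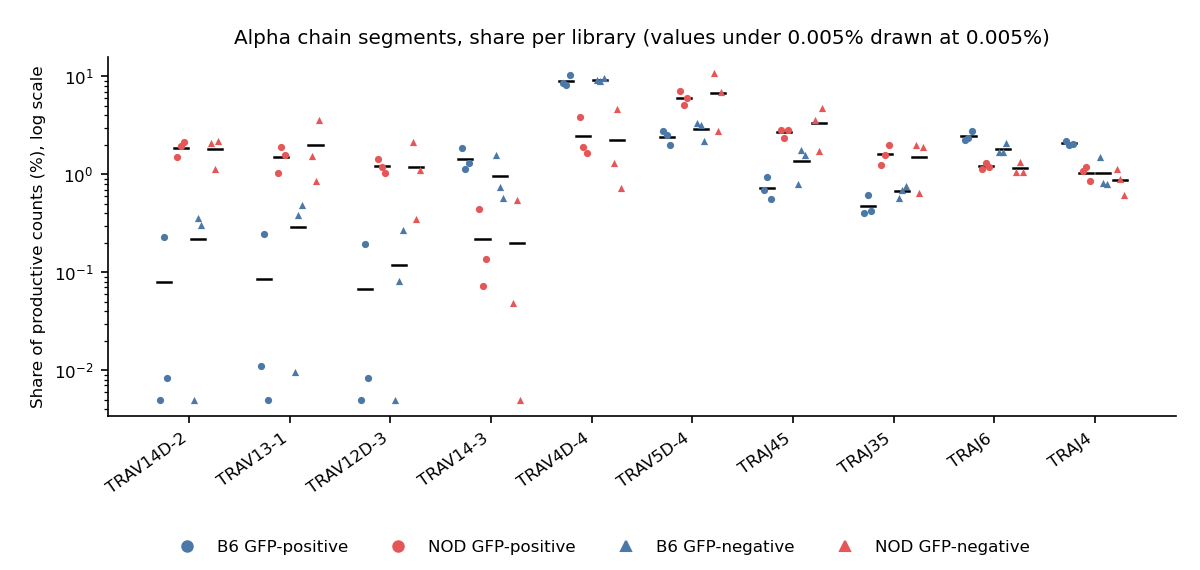
Share of productive counts (%, log scale) of 10 alpha segments in each library, GFP-positive and GFP-negative, B6 and NOD, 3 points per group with a line at the mean; values under 0.005% are drawn at 0.005%. TRAJ45 went from 0.731% in B6 to 2.69% in NOD GFP-positive libraries and TRAJ6 from 2.46% to 1.21%.

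Did the GFP-negative cells of the 2 strains differ in the same way? In the GFP-negative sort 17 segments rose and 9 fell in NOD, 26 of 129 (edgeR, two-sided, adjusted p under 0.05; 51 at p under 0.05): 13 V up, 7 V down, 4 J up, 2 J down. TRAV13-4/DV7 (53757410 to 53757921, mm10) rose from 0.772% ± 0.126 to 2.70% ± 0.800 (n = 3 each, log2 1.83, SE 0.26, adjusted p = 0.00249), and kept its call in all 6 fits with a library left out. TRAV4D-4 (52990889 to 52991389) fell from 9.21% ± 0.312 to 2.22% ± 2.11 (log2 -2.17, SE 0.54, adjusted p = 0.0326). TRAV13N-2 fell from 1.27% ± 0.268 to 0.182% ± 0.274 (log2 -3.30, adjusted p = 0.0420), TRAV13N-1 by log2 -3.21 and TRAV12D-2 by log2 -1.37. TRAV12-2, TRAV6-6, TRAV10D, TRAV16 and TRAV4-2 rose by log2 2.32, 2.28, 1.80, 1.49 and 1.43. TRAV12-2 and TRAV6-6 turned with copies merged. TRAV5D-4 rose again, from 2.92% ± 0.644 to 6.80% ± 3.98 (log2 1.24, SE 0.37, adjusted p = 0.0440), with overlap between the libraries of the strains. No overlap was seen for 38 of 89 V (42.7%) and 10 of 40 J (25%).

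Of the J-alpha segments of GFP-negative cells TRAJ12 (54206552 to 54206610, mm10) fell from 4.10% ± 0.539 to 2.50% ± 0.295 (n = 3 each, log2 -0.73, SE 0.13, adjusted p = 0.00684) and TRAJ6 by log2 -0.68. TRAJ50, TRAJ48 and TRAJ32 rose by log2 0.75, 0.67 and 0.53, and TRAJ45 by log2 1.33 (adjusted p = 0.0385). Many calls of this contrast turned on single libraries: TRAV4D-4 kept its call only when NOD GFP-negative replicate 2 was the library left out, and ended with the 2 groups alone (adjusted p = 0.144). TRAJ12 kept its call in 6 of 6 such fits, and TRAJ50, TRAJ6, TRAJ48 and TRAJ32 in 1. The 26 calls became 4 without B6 GFP-negative replicate 1, 3 without replicate 2 and 3 without replicate 3, 3 without NOD GFP-negative replicate 1, 63 without replicate 2 and 4 without replicate 3. They became 42 with DESeq2, 16 with copies merged, 0 with the 2 groups alone, 50 without clonotypes found in both strains and 0 without the number-1 libraries. Of 19 called V names with copies 8 kept call and direction on merging and 11 did not, 6 of them turning, and 9 of 47 merged V names passed.

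The same lists were tested in the GFP-negative sort. V-distal J-alpha went from 30.8% ± 1.74 in B6 to 25.6% ± 1.67 in NOD (n = 3 each), with 2 of 14 members down, 2 adjusted over the list alone (fry adjusted p = 0.0121; 0.105 without clonotypes of count 1). V-proximal J-alpha went from 18.5% ± 2.70 to 24.1% ± 2.11, with 3 of 9 members up, 3 adjusted over the list alone, and the set did not pass (fry adjusted p = 0.104; 0.00833 without clonotypes found in both strains). Middle J-alpha had 1 of 17 members up, 0 adjusted over the list alone (50.7% ± 1.28 and 50.2% ± 0.469, fry adjusted p = 0.797), with median log2 -0.02, mean 0.01 and fry direction down. Insulin-recognition V-alpha had 1 of 1 up, 1 adjusted over the list alone (2.96% ± 0.648 and 6.82% ± 3.96, fry adjusted p = 0.115; 0.00482 without NOD GFP-negative replicate 2). J-proximal V-alpha had 0 of 3 (5.66% ± 1.60 and 5.63% ± 1.64, fry adjusted p = 0.872; median 0.16, mean -0.08, fry direction down) and J-distal V-alpha 0 of 2 (1.46% ± 0.591 and 1.55% ± 0.269; 0.855), none over the list alone. Duplicated V-alpha copies had 6 up, 6 down and 36 not past the threshold, the same adjusted over the list alone (55.1% ± 2.61 and 49.8% ± 3.15, fry adjusted p = 0.310, mixed 0.00288).

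Did the strain difference depend on the sort? No alpha segment of 129 passed the test of the difference of the strain contrast between the sorts (edgeR 0, with 5 at p under 0.05; DESeq2 0; 1 without NOD GFP-negative replicate 2). Among the lists only middle J-alpha passed, the NOD shift being smaller in GFP-negative cells (median log2 -0.10; 0 of 17 members, 0 adjusted over the list alone, fry adjusted p = 0.0300). That call ended with TMM factors (0.0853), with each clonotype counted once (0.0552), without clonotypes found in both strains (0.0555) and with 9 of 12 libraries left out in turn: all B6 GFP-positive replicates (0.0582, 0.0604 and 0.0605 without replicates 1, 2 and 3), NOD GFP-positive 1 and 2 (0.0894 and 0.104), B6 GFP-negative 1 and 2 (0.0604 and 0.0510) and NOD GFP-negative 1 and 3 (0.0644 and 0.104). V-proximal J-alpha (0.153), V-distal J-alpha (0.160; 0.00705 without clonotypes found in both strains), J-proximal V-alpha (0.428), J-distal V-alpha (0.806), insulin-recognition V-alpha (0.820) and duplicated copies (0.428) did not pass, with 0 members up or down over all segments and over the list alone.

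**Figure D3:**
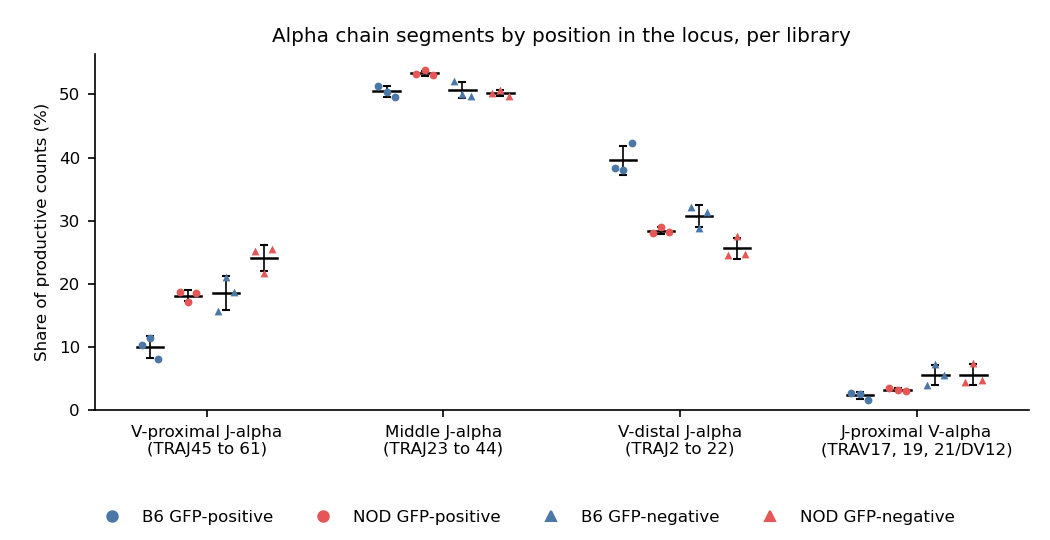
Share of productive alpha counts (%) of the V-proximal, middle and V-distal J-alpha lists and the J-proximal V-alpha list, 1 point per library (circles GFP-positive, triangles GFP-negative; B6 blue, NOD red), line at the mean and bars of 1 SD, n = 3. V-proximal J-alpha went from 9.96% (B6) to 18.2% (NOD) in GFP-positive and from 18.5% to 24.1% in GFP-negative libraries.

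How did alpha usage of GFP-negative cells differ from that of GFP-positive cells? In B6, 6 segments rose and 3 fell (9 of 129; edgeR, two-sided, adjusted p under 0.05): 1 V and 5 J up, 1 V and 2 J down. TRAV21/DV12 (53876016 to 53876752, mm10), a V gene near the J cluster, rose from 0.807% ± 0.266 to 2.79% ± 1.23 (n = 3 each, log2 1.77, SE 0.38, adjusted p = 0.0185), while TRAV14-1 fell from 3.99% ± 0.678 to 1.96% ± 0.162 (log2 -1.03, SE 0.18, adjusted p = 0.0108). TRAJ57 rose from 1.19% ± 0.121 to 2.96% ± 0.642 (log2 1.30, SE 0.24, adjusted p = 0.0108), TRAJ58, TRAJ56, TRAJ48 and TRAJ49 by log2 1.51, 1.18, 0.72 and 0.68. TRAJ15 fell from 4.59% ± 0.214 to 2.60% ± 0.684 (log2 -0.81, adjusted p = 0.0174) and TRAJ13 by log2 -0.54. In NOD no segment passed (edgeR 0, 9 at p under 0.05; DESeq2 1; 11 without NOD GFP-negative replicate 2). No overlap was seen for 16 of 89 V (18.0%) and 16 of 40 J (40%) in B6 and for 5 of 89 V (5.62%) and 11 of 40 J (27.5%) in NOD. The 9 calls of B6 became 14 with DESeq2, 3 without B6 GFP-positive replicate 1, and 0 without B6 GFP-positive replicate 3, B6 GFP-negative replicate 2 or B6 GFP-negative replicate 3.

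The lists by sort showed the shift toward V-proximal J-alpha in GFP-negative cells of B6. V-proximal J-alpha had 5 of 9 members up, 9 adjusted over the list alone (9.96% ± 1.74 to 18.5% ± 2.70, fry adjusted p = 0.00389), V-distal J-alpha 2 of 14 down, 3 over the list alone (39.6% ± 2.33 to 30.8% ± 1.74; 0.00265), and J-proximal V-alpha 1 of 3 up, 2 over the list alone (2.39% ± 0.593 to 5.66% ± 1.60; 0.0115). Middle J-alpha (0 of 17; 0.428), J-distal V-alpha (0 of 2; 0.806), insulin-recognition V-alpha (0 of 1; 0.797) and duplicated copies (0 of 48; 0.872) did not pass in B6. In NOD no member of any list passed; adjusted over the list alone 1 V-proximal J-alpha and 2 J-proximal V-alpha members rose. The NOD sets V-proximal J-alpha and J-proximal V-alpha did not pass (18.2% ± 0.892 to 24.1% ± 2.11; 3.26% ± 0.212 to 5.63% ± 1.64, fry adjusted p = 0.0604 each). V-distal J-alpha passed downward in NOD (28.5% ± 0.527 to 25.6% ± 1.67; 0.0288), as did middle J-alpha (53.4% ± 0.380 to 50.2% ± 0.469; 0.0335). The other NOD sets were J-distal V-alpha (0.428), insulin-recognition V-alpha (0.963; fry direction down, log2 0.19) and duplicated copies (0.248).

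Of the NOD sort calls, V-distal J-alpha ended without clonotypes of count 1 (fry adjusted p = 0.0621) and with any 1 library left out other than NOD GFP-negative replicate 2: 0.0619 (without NOD GFP-negative replicate 1) to 0.104 (without NOD GFP-positive replicate 2). Middle J-alpha ended with each clonotype counted once (0.0552), without clonotypes found in both strains (0.0853), without NOD GFP-positive replicate 1 (0.112) or 2 (0.122), and without NOD GFP-negative replicate 1 (0.0644) or 3 (0.175).

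Did beta segment usage differ between the strains? In GFP-positive cells 1 segment rose and 4 fell in NOD, of 35 (edgeR, two-sided, adjusted p under 0.05). TRBV12-1 (chromosome 6, 41113567 to 41114067, mm10) fell from 9.09% ± 0.728 to 4.13% ± 0.789 (n = 3 each, log2 -1.14, SE 0.23, adjusted p = 0.00648) and TRBV3 from 6.95% ± 0.979 to 4.60% ± 0.213 (log2 -0.60, adjusted p = 0.0314). TRBJ2-4 fell from 11.5% ± 0.441 to 8.80% ± 0.205 (log2 -0.38, SE 0.08, adjusted p = 0.00648), TRBJ1-3 fell by log2 -0.45, and TRBJ2-3 rose from 10.4% ± 0.849 to 12.7% ± 0.326 (log2 0.28, adjusted p = 0.0264). No overlap was seen for 7 of 23 V (30.4%) and 7 of 12 J (58.3%). The 5 calls became 2 without a filter, 1 without clonotypes of count 1, 8 without clonotypes found in both strains and 0 without the number-1 libraries. They became 3 without B6 GFP-positive replicate 2 and 2 without B6 GFP-positive replicate 3, NOD GFP-positive replicate 1 or NOD GFP-positive replicate 2. TRBV12-1 and TRBJ2-4 kept their calls in all 6 such fits and TRBV3 in 1. With the replicate number as a block, 5 segments passed, 4 of them among the 5 above, and TRBV3 ended (adjusted p = 0.0540).

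In GFP-negative cells 4 beta segments rose and 7 fell in NOD, 11 of 35 (1 V up, 5 V down, 3 J up, 2 J down; edgeR, two-sided). TRBV26 (41227525 to 41227913, mm10) fell from 8.24% ± 1.47 to 2.95% ± 1.25 (n = 3 each, log2 -1.5, SE 0.31, adjusted p = 0.00757), TRBV12-2 from 2.97% ± 0.842 to 1.2% ± 0.491 (log2 -1.34, adjusted p = 0.0105), and TRBV23, TRBV12-1 and TRBV3 by log2 -1.74, -0.84 and -0.75. TRBV13-1 rose from 5.26% ± 0.901 to 9.34% ± 1.56 (log2 0.82, SE 0.22, adjusted p = 0.0169). TRBJ2-4 and TRBJ1-3 fell by log2 -0.46 and -0.42, and TRBJ2-1, TRBJ2-3 and TRBJ2-7 rose by log2 0.27, 0.22 and 0.13. No overlap was seen for 8 of 23 V (34.8%) and 6 of 12 J (50%). The 11 calls became 4 without clonotypes of count 1, 7 with the 2 groups alone and 6 without the number-1 libraries. They became 5 without B6 GFP-negative replicate 1, 6 without B6 GFP-negative replicate 3, 7 without NOD GFP-negative replicate 1 and 5 without NOD GFP-negative replicate 2. TRBV26, TRBV12-2, TRBV3, TRBJ2-4 and TRBJ2-1 kept their calls in all 6 such fits, TRBV13-1 in 3 and TRBV23 in 2. No segment passed the difference of the strain contrast between the sorts (edgeR 0 of 35, 1 at p under 0.05; DESeq2 0).

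Mouse mammary tumor virus (Mtv) superantigens engage certain V-beta segments, and those listed as responsive were tested as a set. Mtv-responsive V-beta held 27.5% ± 1.16 of B6 and 19.1% ± 1.36 of NOD GFP-positive counts and 26.6% ± 0.632 and 19.1% ± 2.00 of GFP-negative counts (SD, n = 3 each). Of 5 members 1 fell in GFP-positive cells, TRBV12-1, 2 adjusted over the list alone, and 3 fell in GFP-negative cells, TRBV26, TRBV12-2 and TRBV12-1, 3 over the list alone; the set did not pass (fry adjusted p = 0.0818 in each sort) but did with TMM factors (0.00996 and 0.0138), without clonotypes found in both strains (0.0410 in each sort) and, in GFP-negative cells, without NOD GFP-negative replicate 1 (0.0472); TRBV16 went the other way (log2 0.07 and 0.19). Mtv-7-responsive V-beta, whose superantigen neither strain carries, had 0 of 4 in both sorts, 0 over the list alone (16.1% ± 1.5 and 19.8% ± 3.09; 21.0% ± 1.55 and 23.4% ± 2.89, fry adjusted p = 0.229 and 0.731). The first D-J-beta cluster had 1 of 6 down in each sort, 1 over the list alone (29.2% ± 1.72 and 26.5% ± 1.48; 29.0% ± 1.25 and 26.2% ± 0.374; 0.229 and 0.123). The second cluster had 1 up and 1 down of 6 in GFP-positive cells, 3 and 1 over the list alone, and 3 up and 1 down in GFP-negative cells, 3 and 1 over the list alone (0.520 and 0.594). For the difference between the sorts no member of any list passed, nor over the list alone: Mtv-responsive 0.847 (median 0.12, mean -0.12, fry direction up), Mtv-7-responsive 0.569, first cluster 0.766 and second cluster 0.751.

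**Figure D4:**
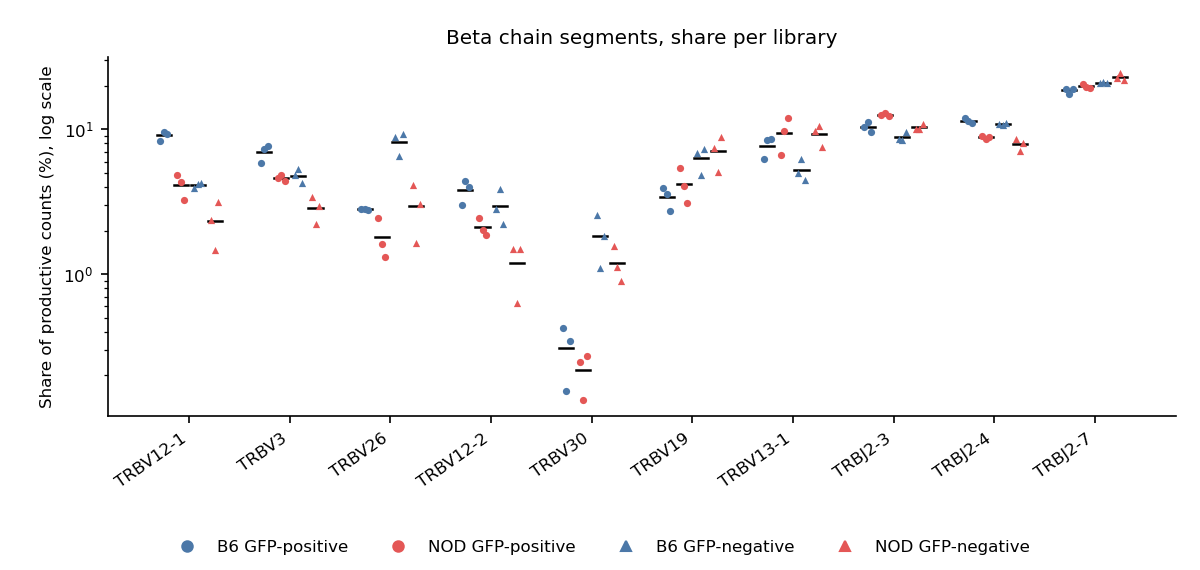
Share of productive counts (%, log scale) of 10 beta segments in each library, GFP-positive and GFP-negative, B6 and NOD, 3 points per group with a line at the mean. TRBV12-1 went from 9.09% in B6 to 4.13% in NOD GFP-positive libraries, and TRBV30 from 0.308% to 1.83% between the sorts of B6.

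Which beta segments marked GFP-negative cells? In B6 4 rose and 3 fell and in NOD 3 rose and 3 fell, of 35 (edgeR, two-sided, adjusted p under 0.05). TRBV30 (41281376 to 41281990, mm10) rose in both strains, from 0.308% ± 0.137 to 1.83% ± 0.718 in B6 (n = 3 each, log2 2.58, SE 0.43, adjusted p = 0.00270) and from 0.219% ± 0.0731 to 1.2% ± 0.334 in NOD (log2 2.42, SE 0.45, adjusted p = 0.00528). TRBV12-1 and TRBV3 fell in both strains, TRBV12-1 from 9.09% ± 0.728 to 4.14% ± 0.163 in B6 (log2 -1.13, adjusted p = 0.00468) and from 4.13% ± 0.789 to 2.32% ± 0.848 in NOD (log2 -0.83, adjusted p = 0.0312), TRBV3 by log2 -0.53 and -0.69. TRBV26 and TRBV19 passed in B6 and not in NOD: TRBV26 rose from 2.80% ± 0.0316 to 8.24% ± 1.47 (log2 1.55, SE 0.30, adjusted p = 0.00468) and TRBV19 from 3.41% ± 0.617 to 6.31% ± 1.33 (log2 0.88, adjusted p = 0.0349). In NOD they went from 1.80% ± 0.578 to 2.95% ± 1.25 (log2 0.71, adjusted p = 0.126) and 4.20% ± 1.15 to 7.13% ± 1.87 (log2 0.77, adjusted p = 0.0581); these rises did not pass against B6 (adjusted p = 0.881 and 0.899). TRBJ2-3 fell by log2 -0.23 in B6 and -0.29 in NOD, TRBJ2-7 rose by log2 0.18 and 0.22, and TRBJ2-1 rose by log2 0.20 in NOD.

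No overlap between the sorts was seen for 8 of 23 V (34.8%) and 7 of 12 J (58.3%) in B6 and 7 of 23 V (30.4%) and 6 of 12 J (50%) in NOD. The 7 calls of B6 became 4 without clonotypes of count 1, 2 without the number-1 libraries and 4 without B6 GFP-positive replicate 2 or B6 GFP-negative replicate 1. The 6 of NOD became 3 with the 2 groups alone, 2 without the number-1 libraries, 2 without NOD GFP-positive replicate 2 and 3 without NOD GFP-negative replicate 1. With 1 library left out TRBV30 and TRBJ2-7 kept their calls in all 6 fits of both strains, and TRBV26 and TRBV12-1 in all 6 of B6. TRBV12-1 kept its call in 2 of 6 in NOD, TRBV3 in 2 in B6 and 5 in NOD, TRBV19 in 2 in B6, TRBJ2-3 in 2 in B6 and 4 in NOD, and TRBJ2-1 in 2 in NOD.

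The V-beta and J-beta lists did not pass as sets between the sorts. Mtv-responsive V-beta had 1 up (TRBV26) and 1 down (TRBV12-1) of 5 in B6, the same over the list alone (fry adjusted p = 0.651), and 1 down in NOD, 1 over the list alone (0.731; median 0.04, mean -0.13, fry direction down). Mtv-7-responsive V-beta had TRBV19 up in B6, 1 over the list alone (0.108), and 0 of 4 in NOD, 1 over the list alone (0.565). The first D-J-beta cluster had 0 of 6 in both, 0 over the list alone (0.731 and 0.567). The second had 1 up and 1 down in B6 and 2 up and 1 down in NOD, the same over the list alone (0.651 and 0.565).

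Was the repertoire of NOD cells less diverse? No measure passed between the strains at equal depth of 2010 alpha or 5192 beta counts. The Shannon effective number of alpha clonotypes was 1643 ± 178 in B6 and 1641 ± 157 in NOD GFP-positive libraries (SD, n = 3 each) and 1536 ± 209 and 1446 ± 391 in GFP-negative ones. For beta it was 4308 ± 138 and 4213.5 ± 215 (GFP-positive) and 3394 ± 264 and 3684 ± 391 (GFP-negative). The inverse Simpson index was 1529 ± 213 and 1526 ± 184, 1315 ± 287 and 1275 ± 449.5 for alpha, and 4025 ± 165 and 3908 ± 247, 2431 ± 451 and 2995 ± 619.9 for beta. Over both sorts no measure of either chain passed between the strains (exact permutation, two-sided, smallest p reachable 0.005; lowest adjusted p = 0.571). Within a sort, 3 libraries against 3, no p was under 0.2 between the strains (smallest reachable 0.1). No diversity or feature measure passed the test of the strain difference between the sorts (18 tests, lowest adjusted p = 0.135).

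GFP-negative cells of both strains had a less even beta repertoire. The Shannon number was 0.830-fold that of GFP-positive cells, the inverse Simpson index 0.680-fold, and the 10 most abundant clonotypes held 3.05-fold the share: 0.753% ± 0.0655 and 0.810% ± 0.0579 in B6 and NOD GFP-positive libraries, 2.76% ± 0.591 and 2.06% ± 0.803 in GFP-negative ones (n = 3 each, exact permutation, two-sided p = 0.005 and adjusted p = 0.0267 for all 3). Distinct beta clonotypes fell 0.897-fold (4523 ± 111 and 4449 ± 177 to 3944 ± 190.2 and 4106 ± 284, exact permutation p = 0.01, adjusted p = 0.0400). For alpha the top 10 share rose 1.74-fold, from 1.85% ± 0.272 and 1.84% ± 0.148 to 3.28% ± 1.29 and 3.12% ± 1.70 (exact permutation p = 0.015, adjusted p = 0.0480), and distinct clonotypes (1730 ± 143 and 1730 ± 127 to 1675 ± 153 and 1575 ± 332), the Shannon number and the Simpson index did not pass (log2 -0.09, -0.14 and -0.24; adjusted p = 0.688, 0.676 and 0.547).

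These sort differences had limits. The alpha top 10 call ended at a fraction 0.5 of the depth (log2 0.55, adjusted p = 0.0960), with V, J and amino acids as the clonotype (0.81; 0.0640), without clonotypes found in both strains (0.40; 0.560), and without any 1 GFP-positive library (0.112 to 0.240). Without the count-1 clonotypes alpha distinct, Shannon and Simpson measures passed as well (log2 -0.30, -0.36 and -0.44; adjusted p = 0.0114 each). The beta Shannon, Simpson and top 10 calls ended without NOD GFP-positive replicate 1 or 3 (adjusted p = 0.0533), and that of distinct clonotypes without any 1 GFP-positive library other than NOD replicate 2 (0.0600 to 0.1). Without clonotypes found in both strains the beta Simpson difference kept its call at log2 -0.28, against -0.56 with them.

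**Figure D5:**
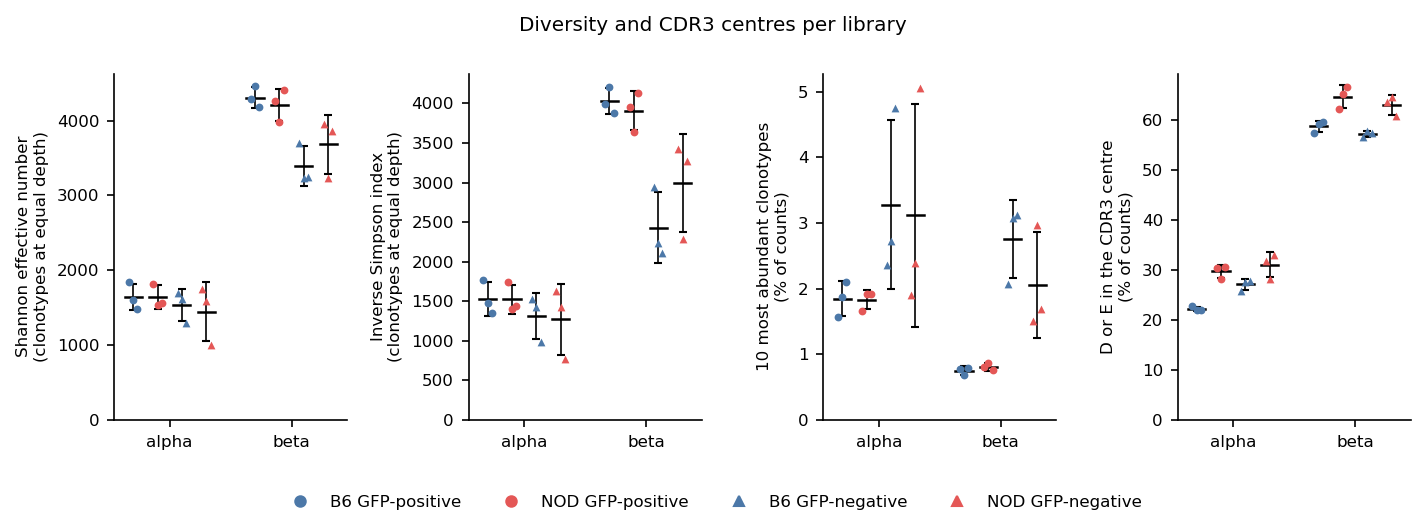
Shannon effective number, inverse Simpson index, share of counts in the 10 most abundant clonotypes (%) and share of clonotype counts with D or E in the CDR3 centre (%), alpha and beta, 1 point per library in 4 groups of 3 with mean and SD. The beta top 10 share was 0.753% and 0.810% in GFP-positive and 2.76% and 2.06% in GFP-negative libraries of B6 and NOD.

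Did the CDR3 of NOD cells differ in its residues? CDR3 centres of NOD held acidic residues more often in both chains and sorts. The share with D or E rose from 22.3% ± 0.408 to 29.8% ± 1.27 in alpha GFP-positive and from 27.1% ± 1.08 to 31.1% ± 2.48 in alpha GFP-negative libraries, 5.73 points over both sorts. In beta it rose from 58.8% ± 1.12 to 64.8% ± 2.35 and from 57.3% ± 0.634 to 63.0% ± 1.96, 5.86 points (n = 3 each, exact permutation, two-sided p = 0.005, adjusted p = 0.0167 for each chain). The net charge of the beta centre fell by 0.141 and beta CDR3 were 0.223 residues longer in NOD (exact permutation p = 0.005, adjusted p = 0.0167 each). Beta CDR3 with an internal cysteine rose by 0.935 points (exact permutation p = 0.01, adjusted p = 0.0286). Alpha charge (-0.0455; adjusted p = 0.05) and beta hydrophobic residues at positions 6 and 7 (0.391 points; adjusted p = 0.05), a feature tied to self-reactivity, did not pass. Alpha length (0.00262 residues; 0.989), alpha cysteine (0.000501 points; 0.990) and alpha hydrophobic residues (0.0553 points; 0.735) did not pass.

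V and J usage gave up to 72.3% (alpha) and 67.7% (beta) of the acidic difference. The acidic rates used, pooled over both strains, can hold strain differences. Left were 1.59 points (p = 0.025) and 1.89 points (p = 0.01, exact permutation, two-sided, n = 12). The alpha call ended with each clonotype counted once (4.63 points, adjusted p = 0.05), and no left-out library ended the acidic calls. The cysteine call was tied to TRBV1: without that segment the difference was 0.0547 points (adjusted p = 0.492). It also ended with each clonotype counted once (adjusted p = 0.0800), without clonotypes of count 1 (0.142), and without any 1 B6 library other than GFP-negative replicate 2 (0.05 to 0.0571).

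Between the sorts, alpha CDR3 of GFP-negative cells were 0.113 residues longer and beta CDR3 0.121 residues shorter than those of GFP-positive cells (exact permutation over both strains, two-sided p = 0.005, adjusted p = 0.0167 each, n = 6 and 6). Alpha acidic share (3.08 points; adjusted p = 0.05), alpha charge (-0.0346; 0.0818), beta cysteine (0.630 points; 0.108), beta acidic share (-1.62 points; 0.154), beta charge (-0.0167; 0.5625), beta hydrophobic residues (-0.122 points; 0.536), alpha cysteine (0.0224 points; 0.828) and alpha hydrophobic residues (-0.0874 points; 0.5625) did not pass. The alpha length call ended without clonotypes of count 1 (0.0937 residues, adjusted p = 0.05) and the beta length call with each clonotype counted once (-0.0875, adjusted p = 0.0571).

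Were the same receptors found in the libraries of a strain? Sharing of amino-acid clonotypes within a strain did not pass against that between strains, but only the latter held same-numbered pairs, so this is open. Overlap was 3.67% ± 1.91 within and 3.69% ± 3.63 between strains for alpha GFP-positive libraries (6 and 9 pairs; exact permutation, one-sided p = 0.6, smallest reachable 0.1), 7.42% and 7.68% for alpha GFP-negative (p = 0.5), 1.68% and 2.11% for beta GFP-positive (p = 0.9) and 4.46% and 4.72% for beta GFP-negative (p = 0.4). By abundance, the Morisita-Horn index times 100 was 10.3 and 8.70 (one-sided exact p = 0.4), 16.1 and 13.6 (p = 0.3), 3.02 and 3.64 (p = 1), and 11.4 and 8.10 (p = 0.2). Without clonotypes of count 1 the alpha GFP-positive log2 ratio of within to between moved from -0.01 to 1.07, and with nucleotide clonotypes the beta GFP-positive ratio moved from -0.33 to -1.02. With 1 library left out the alpha log2 ratio ran from -0.49 to 0.43 (GFP-positive) and -1.03 to 0.64 (GFP-negative). For beta it ran from -0.65 to -0.14 and -0.95 to 0.71, and every one-sided exact p was 0.2 or more. GFP-positive and GFP-negative libraries of the same strain and number shared 7.66% of alpha nucleotide clonotypes against 2.55% for different numbers. The ratio was 3.00 (exact permutation of 36 pairings, one-sided p = 0.0278, the smallest reachable). It came from number 1: 14.4% and 21.7% for B6 and NOD, 2.48% and 1.48% for number 2, 3.11% and 2.87% for number 3. For beta the shares were 0.576% and 0.865% (one-sided exact p = 0.972). Alpha number-1 libraries NOD GFP-positive and B6 GFP-negative shared 35.6%. The alpha ratio lost its call without clonotypes found in both strains (4.48, exact p = 0.0556).

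Public receptors were few. Of 38759 alpha amino-acid clonotypes 68.4% were found in 1 library, 179 in at least 6 and 1 in all 12; of 84117 beta clonotypes 87.7%, 74 and 0. TRBV20 TRBJ2-1 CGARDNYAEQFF rose in GFP-negative cells over both strains (log2 5.09, SE 1.16, adjusted p = 0.000467; 8 of 12 libraries; 0% in B6 and 0.0114% ± 0.0131 in NOD GFP-positive, 0.0363% ± 0.0354 and 0.429% ± 0.383 in GFP-negative libraries, n = 3 each), as did TRBV15 TRBJ1-1 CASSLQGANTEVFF (log2 4.29, SE 1.21, adjusted p = 0.00253; 9 of 12 libraries; 0.00220% ± 0.00381 and 0.0131% ± 0.0159, 0.0549% ± 0.0496 and 0.328% ± 0.141) and TRBV3 TRBJ2-3 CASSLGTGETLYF (log2 4.66, SE 1.91, adjusted p = 0.0276; 4 of 12 libraries; 0.0154% ± 0.0267 and 0%, 0.229% ± 0.289 and 0.0449% ± 0.0778), 3 of 4 beta clonotypes tested (edgeR, two-sided). TRBV26 TRBJ2-7 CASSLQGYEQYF did not pass (adjusted p = 0.0564). Of 6 alpha clonotypes 0 passed between the sorts (edgeR, 3 at p under 0.05, lowest adjusted p = 0.0554; DESeq2 0; 3 with CDR3 amino acids alone). Between the strains in GFP-positive cells 0 alpha (0 at p under 0.05; DESeq2 0; 1 with CDR3 amino acids alone) and 0 beta clonotypes passed (1 at p under 0.05, adjusted p = 0.121; DESeq2 0).

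The shared-clonotype counts turned on single libraries. The 3 beta calls became 1 with at least 10 counts in 3 libraries, 1 without NOD GFP-positive replicate 2, 5 without B6 GFP-negative replicate 1, B6 GFP-negative replicate 2 or NOD GFP-negative replicate 1, 12 without NOD GFP-negative replicate 2 and 6 without NOD GFP-negative replicate 3. The alpha count by sort became 5 without B6 GFP-negative replicate 1, 2 without NOD GFP-negative replicate 1 and 1 without NOD GFP-negative replicate 2.

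Did the sort hold other T cells? Invariant NKT alpha chains, the semi-invariant chain of cells that see CD1d, made up 0.0870% ± 0.0399 of B6 and 0.239% ± 0.159 of NOD GFP-positive counts and 0.386% ± 0.0721 and 0.814% ± 0.905 of GFP-negative counts (SD, n = 3 each). Their share did not pass between the strains (0.290 points, exact permutation, two-sided p = 0.315) or the sorts (0.437 points, p = 0.05). Without NOD GFP-negative replicate 1 both passed (0.475 points, p = 0.015, and 0.623 points, p = 0.005), and without NOD GFP-negative replicate 3 they were 0.0377 points (p = 0.73) and 0.185 points (p = 0.13, exact permutation). That of the sorts also passed with each clonotype counted once (0.126 points, exact permutation p = 0.03) and without clonotypes of count 1 (0.731 points, exact permutation p = 0.04). The chain TRAV11 TRAJ18 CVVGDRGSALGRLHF was the only alpha clonotype found in all 12 libraries. MAIT chains made up 0 to 0.0502% of a library and were absent in 9 of 12 libraries, with 95% upper limits of 0.0246% to 0.149% from counting error, and did not pass between the sorts (-0.00777 points, exact permutation p = 0.8) or strains (-0.00496 points, p = 1). Gamma-delta cells cannot be seen in alpha and beta libraries.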

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

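All tests of explanations in this part, and the splits of samples, were specified after results were seen.

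Middle J-alpha was the only list whose strain difference changed between the sorts (fry adjusted p = 0.0300), with 0 of 17 members past the threshold. It rose in NOD against B6 in GFP-positive cells, from 50.5% to 53.4% of counts, and not in GFP-negative cells, 50.7% and 50.2%. The call ended with 9 of 12 libraries left out in turn and in 3 of 5 other settings, so it may rest on single libraries. The tables also held 99 rows with an out-of-frame CDR3, which were left out of every other result; keeping them changed 0 of 73 calls of named segments.

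Identical nucleotide clonotypes in B6 and NOD libraries have 3 explanations that were tested. With independent recombination as the whole source, the overlap of a pair would follow from its libraries. After the level of each library, log2 overlap of B6 with NOD libraries of a sort kept an SD of 1.80 in alpha and 1.91 in beta, against 0.894 and 0.350 across sorts (18 pairs each, F = 4.07 and 29.9, both past 0.05 in an F-test), which excludes it for both chains. An alpha library labelled with the wrong strain is excluded: among 1-strain clonotypes TRAV4D-4 held at most 1.92% in NOD and at least 7.30% in B6; no such mark was tested for the beta libraries. For sequence carried over between libraries, names that mark B6 made up 15.8% of the alpha clonotypes found in both strains, against 3.95% from usage. That usage was of 1-strain clonotypes, and 64 of 89 names marking neither strain also lay above it (77.3% against 92.3% in all). Names that mark NOD made up 6.86% against 3.74%, 1.84 times and under the 2 times asked for. Of these 8 names 7 lay above usage, TRAV4-2 below (1.52% against 2.06%). Carry-over and chance recombination beside it cannot be told apart for either set. At which step cells, RNA or libraries were mixed, if they were, was not tested. The rule for strain-marking names (1% in a strain, 4 times the other) was set after V usage and TRAV4D-4 were seen.

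More acidic CDR3 centres in NOD were tested against 2 explanations, each excluded as the whole cause if the libraries of the sorts are separate units. After V and J usage 1.59 points remained in alpha and 1.89 in beta, with 4 of 6 alpha and 5 of 6 beta NOD libraries above every B6 library of their sort. With each clonotype counted once the difference was 4.63 and 5.64 points, so a few abundant clonotypes were not its source, though the alpha value had adjusted p = 0.05. A selection of acidic CDR3 within the same V and J pairs is a hypothesis that was left, and it was not tested.

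V-alpha names that differ between the strains may partly reflect counts split between near-identical copies. On merging, 16 called names with copies kept call and direction in GFP-positive and 8 in GFP-negative cells. These differed as merged groups, but which copy differed was not tested. For the 17 and 11 other names, a split and a real difference between copies cannot be told apart. The shift of NOD GFP-positive cells to V-proximal J-alpha could come from fewer successive alpha rearrangements before selection. That hypothesis calls for more J-proximal V-alpha, whose list had fry adjusted p = 0.428, so this and another cause of the shift cannot be told apart.

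Other splits of the samples were compared with the real one. For 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In the alpha chain 1 split, the real one, reached the 48 calls between strains in GFP-positive cells (highest other 0), 1 the 26 in GFP-negative cells (1) and 1 the 9 between the sorts of B6 (3), and all 10 the 0 between the sorts of NOD (1). In the beta chain 1 reached the 5 (0), 1 the 11 (0), 1 the 7 (0) and 1 the 6 (3). For the 5 beta calls the replicate numbers paired the libraries, and the 3 other splits that part every pair gave 0. For shared clonotypes between strains all 10 splits reached the real 0 in alpha (0) and in beta (0).

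For the difference between the sorts and for shared clonotypes by sort 100 splits were drawn. All 100 reached the 0 alpha (highest 44) and the 0 beta segments (highest 11) of the between-sort difference. A real count of 0 makes this certain, so it says nothing about chance. The drawn splits mixed strains and sorts, so the 44 and 11 calls can hold strain and sort differences, and their source was not tested. All 100 reached the 0 alpha shared clonotypes by sort (highest 3), as certain. For the 3 beta shared clonotypes by sort 2 of 100 reached as many, with 3 at the highest. GFP-negative beta libraries shared up to 18.1% of sequences, so chance is not excluded for that count. Nor is it for each clonotype. By sort no calls were simulated, and leaving out 1 library moved the count to between 1 and 12.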

How the results depend on the processing

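The settings without number-1 libraries, without clonotypes found in both strains and without TRBV1, all settings of the lists and of the same-number overlap, and the weighting and count-1 settings of the invariant NKT share, were chosen after results were seen; every other setting was fixed before. The cause of a change under a setting was not tested. Medians of lists in this part are of the log2 CPM differences that fry used, and those in the results are of edgeR log2 ratios, so the values differ.

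The strain and sort contrasts rest on 3 libraries per group, and counts of called segments moved more than 1.5 times in 28 of 72 fits with 1 library left out and in 23 of 103 other settings. Of 73 named segments 49 lost the call without the number-1 libraries, 26 without clonotypes of count 1, 25 with the 2 groups alone, 18 with each clonotype counted once, 17 with the replicate block, 8 without a filter, 6 with TMM factors, 4 without clonotypes found in both strains, 1 with DESeq2 and 0 with out-of-frame rows kept. Leaving out 1 library ended 206 of 438 calls of named segments. For lists without a call 18 of 45 turned direction and 8 gained a call under some setting. With the replicate block no permutation test can reach an adjusted p under 0.05 (smallest reachable 0.0625), so every diversity and feature call ended there whatever the data.

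Merging the D and N copies took alpha strain calls from 48 to 27 (GFP-positive) and 26 to 16 (GFP-negative). Of named segments without D or N it turned TRAV13-1 (log2 4.07 to -0.15), TRAV12-2 (2.76 to -0.30) and TRAV14-3 (-2.69 to 0.23) in GFP-positive. In GFP-negative it turned TRAV12-2 (2.32 to -0.64) and TRAV6-6 (2.28 to -0.18).

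Without nucleotide clonotypes found in both strains, alpha strain calls rose to 74 (GFP-positive) and 50 (GFP-negative), and beta GFP-positive strain calls from 5 to 8. For diversity this setting took the alpha top 10 share by sort from log2 0.80 to 0.40 (adjusted p = 0.560). It took beta strain values over both sorts from 0.02 to -0.0071 (distinct), 0.04 to -0.010 (Shannon), 0.13 to -0.019 (Simpson) and -0.16 to 0.073 (top 10 share), and those of GFP-negative cells from 0.30 to -0.014 (Simpson) and -0.42 to 0.083 (top 10 share). The beta Simpson difference by sort kept its call and went from log2 -0.56 to -0.28. Of the features, alpha length by strain went from 0.00262 to -0.0310 (both sorts) and -0.0136 to -0.0489 (GFP-negative), the alpha acidic share in GFP-positive cells from 7.51 to 9.26 points, and beta hydrophobic residues by strain gained a call (0.391 to 0.432 points, adjusted p = 0.0375). The same-number alpha ratio rose from 3.00 to 4.48 and lost its call (exact permutation, one-sided p = 0.0556). Beta list calls went from 0 to 2 (Mtv-responsive V-beta by strain in each sort, fry adjusted p = 0.0818 to 0.0410). Lists that turned direction were duplicated V-alpha copies, strain GFP-positive (median -0.41 to -0.52, fry direction turned), sort NOD (-0.32 to 0.026) and between-sort difference (-0.32 to 0.13), J-distal V-alpha, strain GFP-negative (0.09 to -0.11) and sort B6 (0.14 to -0.11), and Mtv-responsive V-beta, between-sort difference (0.13 to 0.15, fry direction turned).

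Without the number-1 libraries the calls fell to 18 (alpha strain GFP-positive), 0 (alpha strain GFP-negative), 0 (beta strain GFP-positive), 6 (beta strain GFP-negative), 2 (beta sort B6) and 2 (beta sort NOD). Without TRBV1 the beta internal cysteine difference by strain fell to 0.0547 points (adjusted p = 0.492) over both sorts, 0.122 in GFP-positive and -0.0129 in GFP-negative cells, and turned by sort (0.630 to -0.0219).

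With DESeq2 alpha calls went from 26 to 42 (strain GFP-negative), 9 to 14 (sort B6) and 0 to 1 (sort NOD). With the 2 groups alone they went from 26 to 0 (alpha strain GFP-negative), 11 to 7 (beta strain GFP-negative) and 6 to 3 (beta sort NOD). Without a filter beta strain GFP-positive calls fell from 5 to 2. With CDR3 amino acids alone, alpha shared clonotypes went from 0 to 1 (strain) and 0 to 3 (sort), and with at least 10 counts in 3 libraries beta shared clonotypes by sort fell from 3 to 1. With nucleotide clonotypes the beta GFP-positive overlap ratio went from log2 -0.33 to -1.02. With TMM factors beta list calls went from 0 to 2 (the same Mtv set, to 0.00996 and 0.0138), and the second D-J-beta cluster turned for strain GFP-positive (0.11 to 0.074, fry direction turned) and, with the first cluster, for the between-sort difference (-0.046 to -0.0021 and -0.041 to 0.0033).

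Without clonotypes of count 1, beta calls fell from 5 to 1 (strain GFP-positive), 11 to 4 (strain GFP-negative) and 7 to 4 (sort B6). Alpha diversity by sort gained calls for distinct clonotypes (log2 -0.09 to -0.30), Shannon (-0.14 to -0.36) and Simpson (-0.24 to -0.44), adjusted p = 0.0114 each. Beta strain values turned over both sorts for distinct (0.02 to -0.13), Shannon (0.04 to -0.12) and Simpson (0.13 to -0.084), and in GFP-negative cells for distinct (0.06 to -0.21), Shannon (0.12 to -0.17) and Simpson (0.30 to -0.10). Alpha length by sort lost its call (0.113 to 0.0937 residues, adjusted p = 0.05) and beta cysteine by strain lost its call (0.935 to 1.05 points, adjusted p = 0.142; GFP-negative 0.633 to 1.15). Alpha charge by strain gained a call (-0.0455 to -0.0711, adjusted p = 0.0167; GFP-positive -0.0752 to -0.0998, GFP-negative -0.0159 to -0.0423), and so did the alpha acidic share by sort (3.08 to 3.94 points, adjusted p = 0.0429). The alpha acidic share by strain in GFP-positive cells went from 7.51 to 9.68 points. Alpha cysteine turned by strain (0.000501 to -0.0545) and sort (0.0224 to -0.0488), and beta hydrophobic residues by sort (-0.122 to 0.0306). The alpha GFP-positive overlap ratio went from log2 -0.0058 to 1.07. Lists that turned were middle J-alpha, strain GFP-negative (-0.02 to 0.011), J-distal V-alpha, sort B6 (0.14 to -0.044), insulin-recognition V-alpha, sort NOD (-0.021 to 0.036), and Mtv-responsive V-beta, between-sort difference (0.13 to -0.11).

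With each clonotype counted once, beta length by sort (-0.121 to -0.0875 residues, adjusted p = 0.0571), the alpha acidic share by strain (5.73 to 4.63 points, adjusted p = 0.05) and beta cysteine by strain (0.935 to 0.898 points, adjusted p = 0.0800) lost their calls. In GFP-positive cells alpha charge by strain went from -0.0752 to -0.0553 and the alpha acidic share from 7.51 to 5.56 points, and in GFP-negative cells beta length from 0.204 to 0.170 residues. Alpha length (0.00262 to -0.0173) and alpha hydrophobic residues (0.0553 to -0.0196) turned by strain. Lists that turned were J-proximal V-alpha, strain GFP-negative (0.14 to 0.14, fry direction turned), J-distal V-alpha, strain GFP-negative (0.09 to -0.060) and between-sort difference (0.23 to 0.011, fry direction turned), and duplicated V-alpha copies, sort B6 (-0.07 to -0.0060, fry direction turned). With 3 residues left out at each end, alpha charge by strain in GFP-positive cells went to -0.0534, beta charge in GFP-negative cells from -0.141 to -0.184, and the beta acidic share by sort turned from -1.62 to 1.19 points.

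Without equal depth the beta strain values went from -0.02 to -0.14 (distinct), -0.03 to -0.14 (Shannon) and -0.04 to -0.16 (Simpson) in GFP-positive cells, from 0.06 to -0.42 (distinct) and 0.12 to -0.26 (Shannon) in GFP-negative cells, and from 0.02 to -0.28 (distinct), 0.04 to -0.20 (Shannon) and 0.13 to -0.035 (Simpson) over both sorts. Alpha distinct clonotypes of GFP-negative cells went from -0.09 to -0.44. At equal coverage beta distinct clonotypes went to -0.12 (GFP-positive) and 0.32 (GFP-negative). At a fraction 0.5 of the depth the alpha top 10 share by sort went from 0.80 to 0.55 (adjusted p = 0.0960) and by strain from -0.04 to 0.0019. With V, J and amino acids these values were 0.81 (adjusted p = 0.0640) and 0.0079.

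With the replicate block beta calls fell from 7 to 4 (sort B6) and 6 to 2 (sort NOD). The alpha top 10 share by sort (0.80), and beta distinct (-0.16), Shannon (-0.27), Simpson (-0.56) and top 10 share (1.61) by sort reached adjusted p = 0.1. Alpha length by sort (0.113), the alpha acidic share by strain (5.73), beta length by strain (0.223) and sort (-0.121), beta charge by strain (-0.141), the beta acidic share by strain (5.86) and beta cysteine by strain (0.935) reached adjusted p = 0.2. Of the lists J-proximal V-alpha, strain GFP-negative, turned its fry direction (median 0.14), and V-distal J-alpha, sort NOD, lost its call (median -0.26, fry adjusted p = 0.0288 to 0.0524). The block changed no other count of called segments by more than 1.5 times: strain calls were 45 (alpha GFP-positive), 19 (alpha GFP-negative), 5 (beta GFP-positive) and 9 (beta GFP-negative), of which 44, 19, 4 and 9 were also calls without it.

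With 1 library left out, calls ran from 19 to 38 (alpha strain GFP-positive, 48 with all libraries), 3 to 63 (alpha strain GFP-negative, 26), 0 to 12 (alpha sort B6, 9), 0 to 11 (alpha sort NOD, 0), 0 to 1 (alpha between-sort difference, 0), 2 to 6 (beta strain GFP-positive, 5), 5 to 10 (beta strain GFP-negative, 11), 4 to 9 (beta sort B6, 7) and 2 to 7 (beta sort NOD, 6). Shared clonotypes by sort ran from 0 to 5 (alpha, 0) and 1 to 12 (beta, 3), list calls from 6 to 15 (alpha, 10) and 0 to 2 (beta, 0).

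Left-out diversity values by strain over both sorts ran from log2 -0.10 to 0.037 (alpha distinct), -0.12 to 0.059 (alpha Shannon), -0.13 to 0.11 (alpha Simpson), -0.31 to 0.14 (alpha top 10 share) and -0.00090 to 0.045 (beta distinct). By sort they ran from 0.53 to 0.92 (alpha top 10 share), -0.18 to -0.13 (beta distinct), -0.30 to -0.23 (beta Shannon), -0.64 to -0.47 (beta Simpson) and 1.42 to 1.70 (beta top 10 share). Left-out features by strain ran from -0.0181 to 0.0197 residues (alpha length), -0.0501 to -0.0403 (alpha charge), -0.0235 to 0.0383 points (alpha cysteine), -0.00980 to 0.117 points (alpha hydrophobic residues), 0.714 to 1.07 points (beta cysteine) and 0.334 to 0.484 points (beta hydrophobic residues). By sort they ran from 2.59 to 3.78 points (alpha acidic share), -0.00153 to 0.0603 points (alpha cysteine) and 0.475 to 0.851 points (beta cysteine). The invariant NKT share ran from 0.0377 to 0.475 points by strain (0.290 with all libraries) and 0.185 to 0.623 points by sort (0.437), and by sort passed with each clonotype counted once (0.126, p = 0.03) and without clonotypes of count 1 (0.731, p = 0.04, exact permutation). The same-number alpha ratio ran from 1.86 to 3.54, each with exact one-sided p = 0.0833, the smallest reachable with a number left out.

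Left-out medians of lists for the strains ran, in GFP-positive cells, from -0.59 to -0.23 (duplicated V-alpha copies), and in GFP-negative cells from -0.13 to 0.027 (middle J-alpha), -0.16 to 0.15 (J-proximal V-alpha), -0.27 to 0.36 (J-distal V-alpha) and 0.025 to 0.21 (Mtv-7-responsive V-beta). For the sorts they ran from -0.13 to 0.49 (J-distal V-alpha, B6), -0.11 to -0.039 (duplicated V-alpha copies, B6), -0.071 to -0.011 (first D-J-beta cluster, B6), -0.45 to 0.52 (insulin-recognition V-alpha, NOD) and -0.035 to 0.21 (Mtv-responsive V-beta, NOD). For the between-sort difference they ran from -0.70 to 0.27 (insulin-recognition V-alpha), -0.13 to 0.50 (J-distal V-alpha), -0.00066 to 0.23 (Mtv-responsive V-beta), -0.10 to 0.034 (first D-J-beta cluster) and -0.074 to 0.012 (second D-J-beta cluster).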

Other observations

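The tests of explanations in this part were specified after results were seen; the comparisons they rest on were planned.

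The strains differed in the V-proximal J-alpha list, though in GFP-negative cells the set did not pass. Its mean share was 9.96% in B6 and 18.2% in NOD GFP-positive cells, and 18.5% and 24.1% in GFP-negative cells (n = 3 each). The NOD GFP-positive mean was near the B6 GFP-negative one. Members differed within that list: by strain in GFP-positive cells TRAJ45, TRAJ48 and TRAJ50 rose (log2 1.88, 1.05 and 1.05) and TRAJ53, TRAJ56, TRAJ57 and TRAJ58, nearest to the V genes, did not pass (0.43 to 0.54), while by sort in B6 the last 3 rose. No gradient along the array was tested. TRAJ48 and TRAJ49 rose both in NOD against B6 in GFP-positive cells and in GFP-negative against GFP-positive cells of B6, while in GFP-negative cells TRAJ49 did not pass by strain (log2 0.32, adjusted p = 0.181).

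Beta repertoires of GFP-negative cells were less even and TRBV30 took a larger share (1.83% and 1.2% against 0.308% and 0.219% in B6 and NOD). Submission or processing may be the source.

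As a hypothesis, NOD thymocytes that become regulatory T cells may stop alpha rearrangement at an earlier round than those of B6. The J-proximal V-alpha list, which should rise with it, had fry adjusted p = 0.428 between the strains in GFP-positive cells, so this is open. Alpha usage of double-positive thymocytes before selection, in both strains and from separate animals, would tell a difference in rearrangement from one in selection. As a second hypothesis, germline differences of the V-alpha locus between the strains could set which copy is counted, with 17 called names lost on merging copies in GFP-positive cells. Reads aligned to a NOD assembly of the locus would test this.

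As a hypothesis on the CDR3, selection in NOD may favour acidic centres, since 1.59 points of the alpha and 1.89 points of the beta difference remained after V and J usage. Out-of-frame rearrangements, which are not selected, would show whether the difference is present before selection, but only 99 such rows were listed. The clonotypes found in both strains limit each of these readings. At 15.8% of them against 3.95% expected, V-alpha names that mark B6 leave carry-over between libraries open, as do names that mark NOD (6.86% against 3.74%). Repeat libraries with dual unique indexes from the same RNA would show whether libraries were mixed, and repeat sorts whether cells or RNA were.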
